A study of Homo sapiens with 37 samples.

How the data were processed

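ChIP-seq peak lists of 33 libraries were analysed: 24 of FLAG-tagged ER in T-47D and MCF-7, 6 of OCT1 and 3 of CTCF in T-47D. Cell line, ESR1 genotype (WT, Y537S or D538G), clone number, treatment and antibody were taken from the sample labels. The labels give 2 antibodies for OCT1 without assigning them to samples, and state None as the treatment of the OCT1 and CTCF libraries. One input library of T-47D and 3 of MCF-7 (WT, Y537S and D538G) are labelled but have no list here. The control behind each list is not given in the sources used here.

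Reads were aligned with Bowtie to hg19 (GRCh37) and peaks called with MACS2, per the submitters' processing notes, which give no versions. These notes also name DESeq2, whose role is not given in the sources used here. Each list is for 1 library, so the authors' peaks were called per sample and not on pooled clones. Each deposited peak has a score, which equals 10 times its −log10 p without decimals, a fold enrichment over local background (a ratio within the library), and a −log10 p and −log10 q. The lowest −log10 p over all deposited lists was 10.0091. Scores and folds are the authors' own values per peak and were used here to rank or filter peaks within a list. Folds and −log10 p also served to solve the background expectation described below, which was compared between lists. The deposited summit positions were used for the summit windows.

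Merged sites were made by joining peaks that share at least 1 bp over the lists of a comparison, and a site was present in a library with at least 1 peak in it. Peak numbers were compared on the log2 scale by exact two-sided permutation of the labels within strata (genotype for E2 against DMSO, cell line for mutants against WT). The share of WT E2 sites, the E2 response per clone and the Jaccard index between clones were tested the same way. Sites called in at least 4 libraries were tested by an exact conditional test on the number of calling libraries within strata, with Benjamini-Hochberg adjustment at 0.05. Background overlap was measured with OCT1 lists shifted by 10 kb. Clones are the replicates. Where the labels do not say that clones were handled separately, p-values measure only the spread between these libraries. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

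Read depth is unknown. As a stand-in, a whole-number pileup and a background expectation were solved for each peak from the deposited fold and −log10 p, taking the usual MACS2 forms (fold with 1 added to pileup and background, and a Poisson tail). A match within 0.001 of the deposited −log10 p was found for 84.7% to 99.8% of the peaks examined (at most 3000 per list). The median background expectation grows with reads and fragment length in the library and depends on the control. It does not give read totals.

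Clone numbers were checked as pairs by correlating deviations of site presence from group means. DMSO and E2 libraries of a clone come from the same clone and are pairs, with correlations of −0.12 to 0.13 in T-47D and 0.04 to 0.14 in MCF-7. OCT1 lists of the same number correlated at 0.51 to 0.62, over 0.1 in every pair, and count as pairs too. The tests were planned without pairing, and the pairs entered as an alternative (replicate block). Across genotypes the ER numbers did not pair, except in MCF-7 with E2 (0.12 to 0.21).

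Regions were named by a rule fixed before the data were examined. For each comparison, up to 10 sites per direction were eligible that were called in every library of one group and in none of the other, ranked by the mean fold percentile over the calling lists. Coordinates are 1-based. The rule also foresaw the nearest gene of each site, which was not given because no annotation of hg19 was used here. The regions called in every ER library were chosen after their values were seen.

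The alternatives were a stricter threshold (−log10 p of at least 15.0091), lists trimmed to at most 2000 peaks, windows of 100 bp either side of summits, an overlap of at least 0.5 of the shorter region, other library minimums (2 and 6), chromosomes 1 to 22 and X only, the linear scale, the replicate block and leaving out each library or clone. Alternatives added after seeing the data left out the MCF-7 D538G clone whose peak names carry WT, split the OCT1 lists by spelling, trimmed the OCT1 lists to the shortest, used the WT E2 sites of the other line, scaled the ER peak numbers by the background expectation of each list, and left each clone out of the mean OCT1 overlap with the site set unchanged.

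The tests were tested on simulated data. For list length in mutants and WT without E2, with the real SD between clones (log2 1.18), the exact permutation test passed in 7% of 200 draws with no difference, 21.5% at a log2 difference of 1, 70% at 2 and 95.5% at 3. With call rates of the real libraries, 200 sites present in all E2 and no DMSO libraries were all recovered at the adjusted threshold in the E2 comparison (22743 simulated sites, 12 unchanged ones also called), and 34% of 200 at call rates of 0.9 and 0.1 (1 unchanged one called). In the comparison of mutants and WT without E2, 200 such sites among 7254 gave 0 adjusted calls, and 1000 among 7420 were all recovered, with 18 unchanged ones also called. With E2, 200 such sites among 17959 gave 0 adjusted calls, and 1000 among 18018 also gave 0. Simulated pileups were recovered for 100% of 1000 peaks.

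Motif content and genes near peaks were planned but not run, because a genome or annotation of hg19 was not used here.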

Results

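Estrogen receptor alpha (ER, the product of ESR1) is a transcription factor that binds DNA when estradiol (E2) is present. Y537S and D538G are substitutions in its ligand-binding domain that are known from hormone-resistant breast cancer. The binding of FLAG-tagged ER carrying the wild-type (WT) sequence, Y537S or D538G was mapped by ChIP-seq in T-47D and MCF-7, 2 estrogen-responsive breast cancer cell lines. The title of the series links the mutations to constant receptor activity, which poses the question of how much ER binding the mutants show without ligand. For each line and genotype, 2 clones were deprived of estrogen for 5 days and then given 0.1% DMSO (vehicle) or 10 nM E2 for 1 h. These made 24 ER libraries, 1 per clone and treatment. In untreated T-47D cells, OCT1, an octamer-binding transcription factor encoded by POU2F1, was mapped in 2 clones per genotype (6 libraries). CTCF, an insulator protein, was mapped there in 1 clone per genotype (3 libraries). The 4 input libraries have no peak list here. The 33 peak lists held 451084 peaks, from 394 to 24204 in an ER library, 10932 to 25519 in an OCT1 library and 9352 to 27484 in a CTCF library. Read totals are unknown. The background expectation behind each peak, solved from the deposited values, had a median per list of 0.94 to 10.5 reads. Positions are hg19 and are given without gene names, because no annotation of that build was used here.

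E2 lengthened the ER peak lists of both lines. In T-47D, E2 lists had 3.65 times as many peaks as DMSO lists (log2 difference 1.87, averaged over the genotypes). The list length rose in all 6 clones, and 144 merged sites were called in all 6 E2 libraries and in none of the 6 DMSO libraries, against 0 sites the other way. A site of the opposite kind needed a peak in the WT clone 1 DMSO list of 394 peaks. The E2-only site with the highest mean percentile of fold enrichment within its lists lay on chromosome 6 at 135467539 to 135468190 (percentile 89.9). It was also called in both WT E2 libraries of MCF-7 and in no MCF-7 DMSO library. The next site, on chromosome 13 at 98949878 to 98950690, was called in both WT DMSO libraries of MCF-7, as was a site on chromosome 5 at 132584812 to 132585809. Sites on chromosome 6 at 46942411 to 46943172, chromosome 11 at 46510821 to 46511780, chromosome X at 107550402 to 107551923 and chromosome 1 at 207015091 to 207015727 had no peak in any MCF-7 library. The T-47D difference had the smallest p that 216 permutations within genotype allow (exact two-sided permutation test, p = 0.00926). With DMSO and E2 of a clone kept as a pair (replicate block), p was 0.0312 for the same difference. The exact unpaired p rose above 0.05 without the WT clone 1 DMSO list (log2 1.27, p = 0.0648), the D538G clone 1 DMSO list (1.62, p = 0.0648), the WT clone 1 E2 list (2.21, p = 0.0648), the WT clone 2 E2 list (1.53, p = 0.102) or the D538G clone 2 E2 list (1.61, p = 0.0648).

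In MCF-7 the E2 lists were 2.07 times as long as the DMSO lists (log2 1.05). The lists of 5 of 6 clones were longer with E2, and D538G clone 1 went from 16779 peaks without E2 to 15853 with it. A set of 32 sites was called in all 6 E2 libraries and no DMSO library, against 0 sites the other way. The leading ones lay on chromosome 22 at 39866508 to 39867387 (percentile 76.1), chromosome 2 at 121222480 to 121223207 (75.0) and chromosome 22 at 47434140 to 47434737 (72.2). The last of these had no peak in T-47D. In the WT clones alone, 4623 sites were called in both E2 and neither DMSO library, and 8 sites showed the opposite. Among the leading WT sites, chromosome 16 at 23159668 to 23160287, chromosome 12 at 6387405 to 6388208 and chromosome 19 at 18392359 to 18392915 were called without E2 in all 4 mutant clones of MCF-7. In WT T-47D, 3101 sites were called in both E2 and neither DMSO library, led by chromosome 1 at 17903855 to 17904798 (percentile 99.1). The opposite, which needed a peak in the WT clone 1 DMSO list of 394 peaks, held for 0 sites. The MCF-7 difference had p = 0.0185 (exact two-sided permutation test). In exact permutation tests it had p = 0.0625 with the treatments of a clone paired (replicate block, log2 1.05) and p = 0.0556 without D538G clone 2 (log2 0.98), whose 2 lists carry peak names with WT in them. The E2 response of T-47D exceeded that of MCF-7 by 0.82 on the log2 scale, which did not pass the exact permutation test (p = 0.111).

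**Figure D1:**
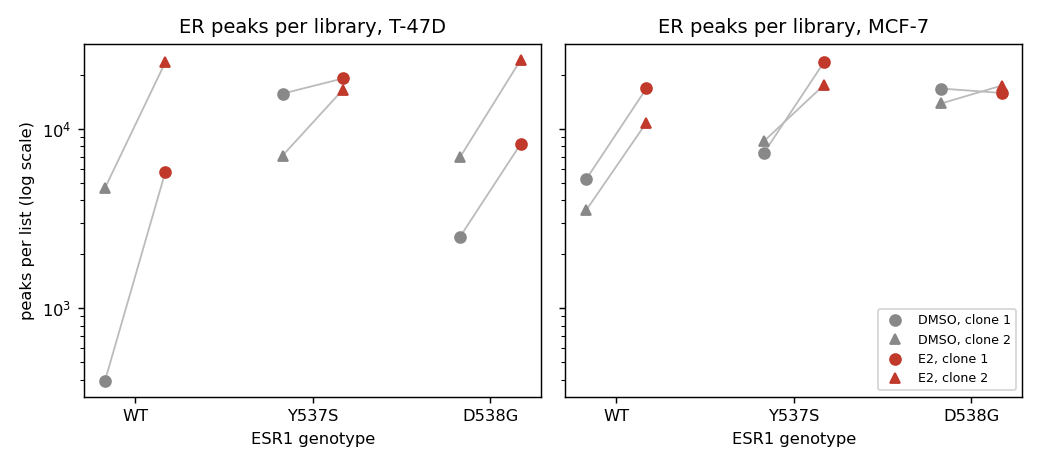
Number of ER peaks (log scale) in each library of T-47D and MCF-7, by ESR1 genotype. Grey points are DMSO and red points E2 libraries, circles clone 1 and triangles clone 2, and a line joins the libraries of a clone. The WT DMSO lists lie at 394 and 4684 peaks in T-47D and at 5223 and 3512 in MCF-7.

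Without E2, mutant ER lists were longer than WT lists by 3.54 times (log2 1.82, 8 mutant and 4 WT clones). In T-47D the 2 WT lists had 394 and 4684 peaks, the Y537S lists 15729 and 7101 and the D538G lists 2510 and 6977. In MCF-7 the WT lists had 5223 and 3512 peaks, the Y537S lists 7315 and 8507 and the D538G lists 16779 and 13865. By their labels, all 4 mutant lists thus exceeded both WT lists. The list of 13865 peaks (D538G clone 2) carries WT in its peak names, and were it WT, it would exceed both Y537S lists. Among the DMSO lists its Jaccard index was highest with D538G clone 1 (0.405), then Y537S clone 2 (0.374) and WT clone 1 (0.333). The label was kept. Mutant ER without E2 was called at more of the sites that WT ER occupied with E2 than WT ER without E2 was. Of the 4910 sites called in both WT E2 libraries of T-47D, DMSO libraries held 21.3% ± 19.4 (SD, n = 2) in WT, 78.2% ± 14.1 (n = 2) in Y537S and 52.6% ± 21.5 (n = 2) in D538G. Of the 9322 such sites of MCF-7, DMSO libraries held 40.6% ± 7.0 (n = 2) in WT, 50.9% ± 3.5 (n = 2) in Y537S and 75.8% ± 3.1 (n = 2) in D538G. The mutant lists held 33.5 percentage points more of these sites than the WT lists over both lines (exact permutation test within line, p = 0.0133), 21.1 points more (p = 0.0356) without the T-47D WT clone 1 E2 list, 19.6 points more (p = 0.00889) with the WT E2 sites of the other line, and 12.9 points more (p = 0.12) when every list was trimmed to its 2000 peaks of highest −log10 p. Of the peaks of each mutant DMSO list, 73.3% to 94.4% in T-47D and 57.6% to 90.6% in MCF-7 lay in a WT E2 peak of either clone of the line, beside 99.7% and 69.9% in the WT DMSO lists of T-47D and 92.7% and 99.3% in those of MCF-7. This share was lower in mutants by −10.9 points, which did not pass the exact permutation test (p = 0.231), with −0.41 points in T-47D and −21.4 in MCF-7. WT E2 peaks called in all 4 mutant DMSO libraries of their line were strong in their own lists, with median fold percentiles of 78.8 and 84.7 in the 2 T-47D lists and 84.0 and 76.2 in the MCF-7 lists. Those called in no mutant DMSO library had medians of 36.3 and 39.9 in T-47D and 31.1 and 33.9 in MCF-7. WT DMSO lists were not examined in this way. Over all genotypes, E2 peaks missing from the other clone's E2 list also ranked lower, by −34.3 percentile points in T-47D and −33.1 in MCF-7. The pattern is therefore not shown to be particular to mutants.

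**Figure D2:**
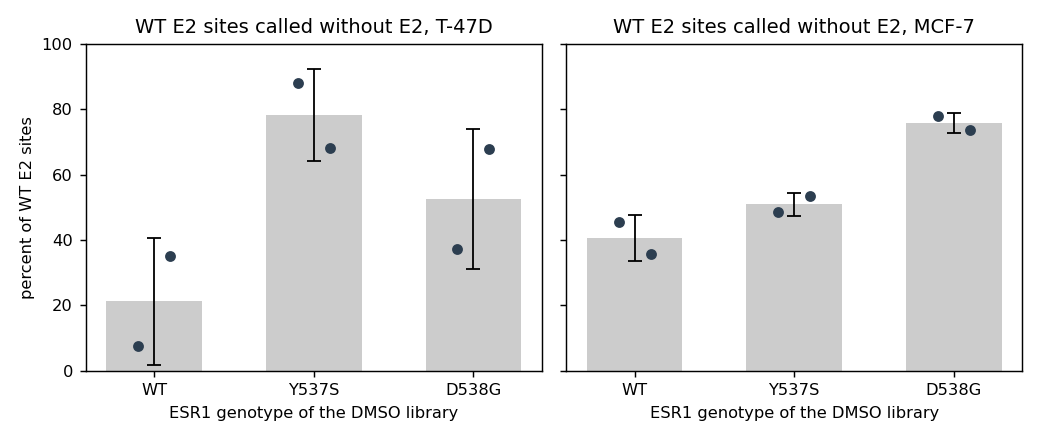
Percent of the sites called in both WT E2 libraries of a line (4910 in T-47D, 9322 in MCF-7) that overlapped a peak of each DMSO library. Points are clones, bars the mean and error bars the SD of 2 clones. The T-47D means are 21.3% in WT, 78.2% in Y537S and 52.6% in D538G.

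Across both lines, 24 sites were called without E2 in all 8 mutant libraries and in none of the 4 WT libraries, and 0 in all WT and no mutant library. The leading 2 lay on chromosome 4 at 75504674 to 75505696 (mean fold percentile 93.6) and on chromosome 19 at 18392093 to 18393070 (92.0). The chromosome 19 region carried an OCT1 peak in all 6 OCT1 lists and a CTCF peak in 1 of 3. Regions on chromosome 4 at 153857007 to 153857725, chromosome 19 at 39900004 to 39900567, chromosome 19 at 3387654 to 3388365 and chromosome 6 at 167041031 to 167041834 carried OCT1 peaks in 4 to 6 lists. Regions on chromosome 13 at 109739669 to 109740823 and at 43806395 to 43807660, and chromosome 6 at 38229323 to 38230231, carried none. All 9 of these ER sites were called in both WT T-47D libraries with E2. Within lines the counts were 682 mutant-only sites against 0 in T-47D and 514 against 1 in MCF-7. Sites of the opposite kind in T-47D and over both lines needed a peak in the T-47D WT clone 1 list of 394 peaks. That list shared 282 sites with WT clone 2, so list length limits these opposite counts. The mutant-only T-47D sites were led by chromosome 2 at 134250288 to 134251662 (98.7), chromosome 6 at 121508456 to 121509514 (98.6) and chromosome X at 115416429 to 115417225 (98.6), all 3 of them called in every WT library of MCF-7. The MCF-7 sites were led by chromosome 8 at 56860921 to 56861481 (93.1) and chromosome 1 at 94374196 to 94374786 (91.7). The single MCF-7 site of the opposite kind, on chromosome 14 at 42071613 to 42071896, had a fold percentile of 20.8.

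The difference in list length without E2 passed the exact permutation test (p = 0.0178, 225 permutations within line). It rested on the T-47D WT clone 1 list of 394 peaks, without which it was 0.93 on the log2 scale (p = 0.173, exact permutation test). The mutant excess was 4.90-fold in T-47D and 2.56-fold in MCF-7, where an exact test of 4 against 2 clones cannot go below p = 0.0667. Peak names in the T-47D lists come in 2 styles, one shared by the Y537S lists and WT clone 2 and one by the D538G lists and WT clone 1. Within these styles the mutant excess was 2.26-fold (2 against 1 library) and 10.6-fold (2 against 1). Within the MCF-7 lists whose peak names give the cell line it was 2.37-fold (3 against 2). These leave out D538G clone 2, whose peak names carry WT.

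With E2, mutant lists were 1.36 times as long as WT lists (log2 0.44), a difference that did not pass the exact permutation test (p = 0.284). Its sign turned without the T-47D WT clone 1 E2 list (log2 −0.06, p = 0.88), and it passed without the WT clone 2 E2 list (0.95, p = 0.0267, exact permutation test). The response to E2 was smaller in the mutants on average. The lists of the WT clones grew 8.58-fold in T-47D (log2 3.10 ± 1.09, SD, n = 2) and 3.15-fold in MCF-7 (1.66 ± 0.04, n = 2). Those of Y537S grew 1.68-fold (0.75 ± 0.67, n = 2) and 2.58-fold (1.37 ± 0.45, n = 2), and those of D538G 3.37-fold (1.75 ± 0.06, n = 2) and 1.09-fold (0.12 ± 0.29, n = 2). The list of MCF-7 Y537S clone 1 grew 3.22-fold, as much as those of the MCF-7 WT clones (3.22-fold and 3.09-fold). Every other mutant clone grew less than both WT clones of its line. The mean mutant response was lower than the WT response by −1.38 on the log2 scale (exact permutation test on 12 clones, p = 0.0133). Without T-47D WT clone 1 it was −0.99 (p = 0.0667, exact permutation test), and on the linear scale −2831 peaks (p = 0.484). Only 2 sites were called with E2 in all 8 mutant and no WT library, on chromosome 5 at 159489174 to 159489632 (percentile 62.2) and chromosome 2 at 215259716 to 215260229 (54.1), and 0 the other way.

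No single site passed the Benjamini-Hochberg threshold in an exact conditional test on the number of calling libraries. For E2 against DMSO, 25654 of 56992 merged sites were tested, with 4190 higher and 0 lower with E2 at an unadjusted p under 0.05 (lowest adjusted p 0.206), and 6579 higher without the T-47D WT clone 1 E2 list. With DMSO and E2 of a clone kept as a pair (replicate block), 2366 were higher and 0 lower (lowest adjusted p 0.342). For mutants against WT without E2, 346 of 8562 sites were higher and 0 lower at that level (lowest adjusted p 0.470). A lower call there needed a peak in all 4 WT lists, of which T-47D WT clone 1 held 394 peaks, so the 0 is no even test of direction. Without the T-47D WT clone 1 DMSO list 189 were higher, and without the MCF-7 WT clone 2 DMSO list 194. With E2 these were 112 higher and 5 lower of 20799 (lowest adjusted p 1). The balance turned to 54 higher and 130 lower without the T-47D WT clone 1 E2 list. It was 302 and 3 without T-47D WT clone 2, 270 and 3 without T-47D D538G clone 1, 53 and 4 without MCF-7 WT clone 1 and 39 and 7 without MCF-7 WT clone 2.

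Sites bound in both clones of a mutation, with or without E2, and in neither WT clone under either treatment numbered 2080 in T-47D and 7731 in MCF-7. In T-47D, 1403 of them belonged to Y537S, 894 to D538G and 217 to both mutations, against 43 sites called in both WT clones and no mutant clone. In MCF-7, 5220 belonged to Y537S, 3609 to D538G and 1098 to both, against 394 WT-only sites. The rules are unlike: a mutant-enriched site could be called in the other mutation, a WT-only site in no mutant clone. Sites called in both clones of 1 genotype and in no other clone of the line numbered 524 (Y537S), 453 (D538G) and 43 (WT) in T-47D. In MCF-7 they numbered 2401, 1712 and 394. Sites called in every mutant library of a line and no WT library, under both treatments, were few. There were 12 in T-47D, led by chromosome 10 at 9087227 to 9088018 (percentile 85.8) and chromosome 18 at 14784088 to 14784512 (71.1), and 19 in MCF-7. The MCF-7 sites were led by chromosome 4 at 22031151 to 22031967 (77.2) and chromosome 19 at 41337700 to 41338289 (75.5). The chromosome 18 site was called in both WT clones of MCF-7 and the chromosome 19 site in WT T-47D. T-47D mutant-enriched sites were called in 29.1% ± 3.6 (SD, n = 4) of cases in a mutant MCF-7 clone and 17.1% ± 9.0 (n = 2) in a WT one. MCF-7 mutant-enriched sites were called in 23.8% ± 10.2 (n = 4) of cases in mutant and 17.0% ± 17.5 (n = 2) in WT T-47D clones. The count of sites called in all 4 mutant clones and neither WT clone ranked 3 among the 15 choices of a reference pair in T-47D, where WT clone 1 with D538G clone 1 as reference gave 4532. In MCF-7 it ranked 1 of 15. By the count of sites absent from the reference pair and called in 2 or more other clones, the WT pair ranked 7 of 15 in T-47D (3281 sites, highest 13973) and 1 of 15 in MCF-7 (9325). With lists of at most 2000 peaks, 568 sites against 43 in T-47D and 637 against 170 in MCF-7 met the rule. The T-47D WT clone 1 DMSO list stayed at 394 peaks there. The T-47D contrast turned without WT clone 1, with 2440 mutant-enriched against 5244 WT-only sites. Without T-47D WT clone 2 the counts were 11102 against 105, without D538G clone 1 8882 against 46, without D538G clone 2 2244 against 117, without Y537S clone 1 2946 against 70 and without Y537S clone 2 4685 against 49. In MCF-7 they were 13528 against 428 without Y537S clone 2, 11750 against 547 without D538G clone 2, 11162 against 734 without D538G clone 1, 11517 against 693 without WT clone 1 and 8415 against 1634 without WT clone 2; such counts rise by construction when fewer clones must meet the rule.

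The order of the 2 mutations in list length without E2 was opposite in the 2 lines, with the T-47D difference near 0 once scaled by the background expectation of the lists. Unscaled, Y537S lists were longer than D538G lists by 1.34 on the log2 scale in T-47D and shorter by −0.95 in MCF-7. The stratified difference was 0.19 (exact permutation test, p = 0.778), and the line-by-mutation difference of 2.29 had the smallest p that 36 permutations allow (exact test, p = 0.0556). In T-47D, 290 sites were called in all 4 Y537S libraries and no D538G library, led by chromosome 4 at 10070505 to 10071212 (percentile 93.6) and chromosome 7 at 64940450 to 64941176 (93.5). The opposite held for 32, led by chromosome 5 at 161863119 to 161863570 (86.1). In MCF-7 the counts were 19 and 534. A D538G-only site of T-47D needed a peak in a list of 2510 peaks, the shortest Y537S list having 7101. A Y537S-only site of MCF-7 needed one in a list of 7315 peaks, the shortest D538G list having 13865. List length thus limits the smaller count in each line. The D538G-only sites of MCF-7 were led by chromosome 11 at 9105461 to 9106046 (89.3) and chromosome 10 at 61791142 to 61791821 (88.9), both called in both WT E2 libraries. The Y537S-only ones were led by chromosome 6 at 43878392 to 43878918 (75.1). No site separated the mutations in both lines. In T-47D the Y537S lists without E2 had a median background expectation of 8.58 and 8.06 reads, and the D538G lists 2.21 and 2.86. With peak numbers scaled by this expectation, Y537S minus D538G was 0.016 on the log2 scale in T-47D and −0.73 in MCF-7. The stratified difference then turned to −0.36 (p = 0.611), and the line-by-mutation difference was 0.75 (p = 0.5), both in exact permutation tests. The mean Jaccard index was 0.485 in T-47D and 0.524 in MCF-7 for clones of one mutation, and 0.419 and 0.412 for clones of different mutations. This difference of 0.089 did not pass (exact permutation test, p = 0.111; the smallest possible is 0.0556). It was 0.0098 (exact p = 1) without T-47D Y537S clone 1, 0.021 (exact p = 0.889) without T-47D Y537S clone 2 and 0.197 (exact p = 0.111) without T-47D D538G clone 2.

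The lines shared part of their WT binding. Of the 4910 WT E2 sites of T-47D, 2465 (50.2%) overlapped a WT E2 site of MCF-7, and 2526 of the 9322 MCF-7 sites (27.1%) overlapped one of T-47D. Without the T-47D WT clone 1 list of 5769 peaks these shares were 24.1% and 61.2%, and without the MCF-7 WT clone 2 list 61.8% and 18.7%. Over all genotypes and treatments, 398 sites were called in all 12 MCF-7 and no T-47D libraries. They were led by chromosome X at 106586283 to 106587439 (percentile 98.6), chromosome 7 at 156538834 to 156540001 (97.3) and chromosome 13 at 69319032 to 69320433 (97.3). The opposite held for 5 sites, on chromosome 12 at 2884098 to 2886559, chromosome 18 at 56720245 to 56721215, chromosome 7 at 41955955 to 41956916, chromosome 14 at 94805542 to 94807840 and chromosome 17 at 56025293 to 56026842. A T-47D-only site needed a peak in the T-47D WT clone 1 DMSO list of 394 peaks, whereas the shortest MCF-7 list had 3512. List length therefore limits the smaller count, and the 2 counts are no even comparison of the lines. An ER peak was called in every one of the 24 libraries at 194 sites. Those with the highest percentiles lay on chromosome X at 16679689 to 16681765 (98.7) and chromosome 2 at 100252572 to 100253915 (98.5).

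OCT1 lists of T-47D mutants were 1.56 times as long as WT lists (log2 0.64), which did not pass the exact permutation test (p = 0.133; the smallest possible is 0.0667). The peak names spell OCT1 in one way for clone number 1 and in another for clone number 2. Within clone number 1, Y537S had 1.31 and D538G 2.33 times the WT peaks, and within number 2, 1.54 and 1.27 times. A set of 416 sites was called in all 4 mutant libraries and neither WT library, against 1 of the opposite kind, on chromosome 1 at 204701064 to 204701482. The leading mutant-only sites lay on chromosome 19 at 34992440 to 34992788 (percentile 92.9), chromosome 15 at 100468592 to 100468933 (90.3) and chromosome 1 at 248100230 to 248100622 (90.0). All 3 carried a CTCF peak in the 3 CTCF lists and no ER peak. The next sites, on chromosome 3 at 52321703 to 52322176 and chromosome 19 at 40949010 to 40949469, carried no CTCF peak. Among the 15 choices of a reference pair, 416 ranked 3, and among the 9 pairs with one list of each clone number it ranked 1, the next being 38. With all OCT1 lists trimmed to the shortest it was 66 against 16, and with 2000 peaks per list 13 against 6. Without WT clone 1 the counts were 864 mutant-only against 325 WT-only sites, without WT clone 2 2423 against 755, without Y537S clone 1 863 against 1, without Y537S clone 2 456 against 5, without D538G clone 1 454 against 4 and without D538G clone 2 749 against 2. D538G lists alone held 64 sites that were in no other OCT1 list, led by chromosome 13 at 114780725 to 114781388 (82.5), and 7 sites were called in the 4 other lists but not in D538G.

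**Figure D3:**
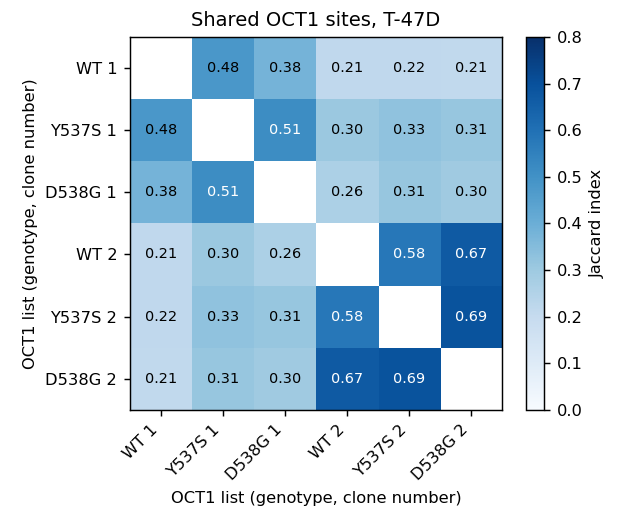
Jaccard index (sites shared by 2 OCT1 lists divided by sites in either) for each pair of the 6 OCT1 lists of T-47D, named by ESR1 genotype and clone number. Pairs of the same clone number average 0.553 and pairs of different number 0.273.

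OCT1 lists of one clone number shared more sites than lists of one genotype. The mean Jaccard index was 0.553 ± 0.119 (SD over 6 pairs) for lists of the same number and 0.273 ± 0.048 (9 pairs) across numbers, and 0.278 ± 0.058 for the 3 pairs of one genotype. ER and OCT1 occupied many common regions. Of 75038 sites merged over all T-47D lists, 35713 had an ER and 33480 an OCT1 peak, 13798 had both, and 6737 also had CTCF. In WT clone 1, 26.4% of DMSO and 19.5% of E2 ER peaks overlapped an OCT1 peak of that clone, and in WT clone 2 42.7% and 8.0%. These shares were 24.4% and 15.2% in Y537S clone 1, 14.9% and 17.5% in Y537S clone 2, 50.6% and 26.0% in D538G clone 1 and 39.2% and 28.7% in D538G clone 2. OCT1 lists shifted by 10 kb overlapped 0.76% to 2.95% of them. The DMSO share was the higher one in 5 of 6 clones, by a mean of 13.9 points (exact sign permutation test, p = 0.0625). T-47D ER peaks also overlapped CTCF lists. For DMSO peaks the shares were 12.8% to 40.7% with the Y537S CTCF list, 6.7% to 16.7% with WT and 0.93% to 2.79% with D538G. With E2 they were 4.9% to 26.5%, 2.9% to 12.9% and 0.60% to 2.70%. OCT1 peaks overlapped the Y537S CTCF list in 44.2% to 63.4% of cases. Overlap of ER with OCT1 is therefore not shown to be special to these 2 factors. Mutant-enriched ER sites overlapped OCT1 peaks of their clone in 21.0%, 23.7%, 10.5% and 24.1% of cases (Y537S clones 1 and 2, D538G clones 1 and 2). Sites also called in WT did so in 18.9%, 16.6%, 33.6% and 20.4%. The mean difference was −2.57 points (exact sign permutation test, p = 1; the smallest possible is 0.125). With D538G clone 1 left out of the mean it turned to 4.29 points (exact p = 0.25, the smallest possible for 3 clones). It was 15.5 points when the mutant-enriched set was also rebuilt without that clone, which raised it from 2080 to 8882 sites.

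CTCF binding has no replicates. Of the 25539 CTCF sites called in WT T-47D, 70.2% (95% Wilson interval 69.6 to 70.7) were called in Y537S and 23.1% (22.6 to 23.6) in D538G. The D538G list was shorter, with 9194 merged sites against 27459 in Y537S, and 64.1% (63.1 to 65.0) of its sites were called in WT, beside 65.3% (64.7 to 65.8) of the Y537S sites. All 3 lists shared 5351 sites. WT peaks also called in D538G had a median fold percentile of 76.5 and the others 42.6. The median background expectation was 2.89 reads in WT, 2.15 in Y537S and 0.94 in D538G. With 2000 peaks per list the shares were 51.5% and 40.6%. The intervals cover counting error only, and no test across genotypes is possible with 1 library each.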

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

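The tests of the short WT list, of the naming styles and of the background expectation were chosen after the results were seen.

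The E2 response of the ER list length differed between mutant and WT clones, by −1.38 on the log2 scale (exact permutation test, p = 0.0133), with the mutant lists longer than the WT lists mainly without E2. A difference in read depth stays open, because the background expectation of a list does not give its read total. Scaled by this expectation (slope 0.77 within groups), the mutant excess without E2 was 1.58 (p = 0.0178, exact permutation test) against 1.82 unscaled. Without the T-47D WT clone 1 list the slope was 0.40 and the scaled excess 0.92 (p = 0.12, exact permutation test). Preparation batches, of which the naming styles of the lists are a possible trace, stay open: the mean within-style excess was 1.94 ± 1.27 (SD over 3 styles), but only 1 style holds more than 1 WT list, and within T-47D each style holds 1 mutation. The T-47D WT clone 1 DMSO list of 394 peaks stays open as a cause of the size: without it the excess was 0.93 (p = 0.173, exact permutation test), and a weak library cannot be told apart from low WT binding there. The MCF-7 excess of 2.56-fold does not involve that list. It was 2.37-fold without D538G clone 2, whose peak names carry WT. MCF-7 has a separate input library for each genotype, and the control behind each list is not given. A control that differs with genotype therefore stays open there. Constant activity of the mutants remains a hypothesis.

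The order of the mutations without E2 was opposite in the 2 lines. Both Y537S lists exceeded both D538G lists in T-47D, by as little as 0.03 on the log2 scale for the closest pair, and lay below both in MCF-7. The line difference was 2.29 on the log2 scale (exact permutation test, p = 0.0556, the smallest possible), and 0.75 (exact p = 0.5) once scaled by the background expectation, with Y537S minus D538G then at 0.016 in T-47D and −0.73 in MCF-7.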

How the results depend on the processing

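Of 284 alternatives, 259 were chosen before the data were examined and 25 after; 235 kept the direction and side of the threshold or the size of the result. The cause of the changes was not tested unless named. Gene-list and motif results and their alternatives were not run. A test that did not pass and again did not pass counts among the 235. So do 31, 19 and 19 alternatives of the 3 counts of single sites past the adjusted threshold, which were 0 in every alternative run. For mutants against WT these show no stability: with E2 the test recovered 0 of 1000 fully separated simulated sites, and without E2 0 of 200, though all of 1000.

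On the linear scale the E2 response difference was −2831 peaks (exact p = 0.484) and the Y537S minus D538G difference turned to −370 peaks. Scaled by the background expectation it turned to −0.36 (exact p = 0.611). Lists of at most 2000 peaks gave a share difference of 12.9 points (exact p = 0.12), mutant-enriched counts of 568 (T-47D), 637 (MCF-7) and 13 (OCT1), shared WT E2 sites of 46.3% (T-47D) and 33.8% (MCF-7), and CTCF sharing of 51.5% (Y537S) and 40.6% (D538G). Shorter lists lower the counts by construction, and the T-47D WT clone 1 DMSO list stayed at 394 peaks. Summit windows gave 25.0% for MCF-7 sites in T-47D and 67.7% and 22.4% for CTCF. CTCF sharing with D538G was 22.2% at the stricter threshold and 22.4% with an overlap of 0.5. OCT1 lists trimmed to the shortest gave 66. Without MCF-7 D538G clone 2, the MCF-7 E2 difference was 0.98 (exact p = 0.0556) and the MCF-7 enriched count 11750.

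With the replicate block the log2 difference of 1.05 in MCF-7 had an exact p = 0.0625; the paired T-47D difference of 1.87 had p = 0.0312, and the OCT1 difference of 0.64 p = 0.222, where the block allows no p below 0.111. In exact tests, blocks on clone number across genotypes, where numbers pair only in OCT1 and MCF-7 with E2, left the differences at 1.82 (p = 0.0123), 0.44 (p = 0.222), 33.5 points (p = 0.037) and 0.19 (p = 0.875) on the same side of the threshold; unadjusted site calls under the block were 2366 with E2, 199 in mutants without E2 and 64 higher in mutants with E2. The block changed no other call.

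Leaving out each library or clone in turn gave 1.27 to 2.46 for E2 in T-47D (exact p above 0.05 in 5 of 12) and 0.94 to 1.16 in MCF-7. The mutant difference was 0.93 to 2.72 without E2 (lowest without T-47D WT clone 1), −0.064 (without T-47D WT clone 1) to 0.95 with E2 and −1.77 to −0.99 for the E2 response. The share difference was 21.1 (without the T-47D WT clone 1 E2 list) to 40.3 points. Y537S minus D538G was −0.18 to 0.56, negative also at −0.09 without T-47D Y537S clone 1, and the sharing difference 0.0098 (without T-47D Y537S clone 1) to 0.197. Enriched counts were 2244 to 11102 (T-47D), 8415 to 13528 (MCF-7) and 454 to 2423 (OCT1). WT E2 site sharing was 24.1% to 61.8% (T-47D) and 18.7% to 61.2% (MCF-7), the OCT1 list length 0.47 to 0.75, and OCT1 at enriched sites −4.80 to 15.5 points, highest without T-47D D538G clone 1, where the enriched set also grew from 2080 to 8882 sites; left out of the mean alone, that clone gave 4.29 points (exact p = 0.25).

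Depth limits all counts: peaks just under the calling threshold are absent from the lists, and a site missing from a list was not detected there rather than unbound.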

Other observations

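The tests of copy number and of genotype, the comparison of missing peaks with the other clone, and the splits within clones were chosen after the result was seen.

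Some DMSO peaks were missing from the E2 list of the same clone. In T-47D, 12.5% ± 12.7 (SD, n = 6 clones) of the DMSO peaks were missing from it, from 1.0% in WT clone 1 to 32.7% in WT clone 2, and in MCF-7 16.9% ± 13.2 (n = 6), from 1.3% in WT clone 2 to 36.4% in D538G clone 1. From the E2 list of the other clone of the same genotype, 21.8% ± 24.1 were missing in T-47D and 22.2% ± 11.9 in MCF-7, and from its DMSO list 42.6% ± 35.9 and 35.7% ± 11.4 (n = 6 each). These shares also follow the length of the second list: of the WT clone 2 peaks of T-47D, 93.8% were missing from a list of 394 peaks and 32.7% from one of 23566. A loss due to E2 is therefore not shown by them. In T-47D the peaks missing with E2 overlapped the OCT1 list of their clone in 52.8% ± 26.8 of cases and the other peaks in 28.3% ± 10.3. The difference of 24.5 points was positive in 5 of 6 clones (exact sign permutation test, p = 0.0625). For peaks missing from the other clone's DMSO list this difference was 0.13 ± 21.4 points, positive in 2 of 6 clones, and lower than with the E2 list of the same clone by 24.4 ± 10.3 points in all 6 (exact sign permutation test, p = 0.0312, the smallest possible). For peaks missing from the other clone's E2 list it was 9.17 ± 40.4 points, positive in 3 of 6, with a CTCF difference of 25.3 points, positive in all 6 T-47D clones. Only 4 peaks of WT clone 1 and 90 of Y537S clone 2 were missing with E2.

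The peaks missing with E2 may be regions that are recovered with any antibody, because they also overlapped CTCF peaks more often than the other peaks did in all 6 T-47D clones, by 29.0 points (exact sign permutation test, p = 0.0312, the smallest possible). In WT clone 1 this rests on 4 missing peaks, and in MCF-7 the same difference was 7.55 ± 13.4 points, positive in 3 of 6 clones (exact p = 0.312). The peaks missing with E2 ranked lower in fold than the others, by −25.3 percentile points in T-47D and −30.9 in MCF-7, each in all 6 clones. Whether weakness alone accounts for the OCT1 difference stays open. Peaks missing from the other clone's DMSO list ranked as low (−26.6 points in T-47D) without that difference, but that list is of another clone and another length. In the upper part of the lists (percentile 50 and above) only overlap with any OCT1 list was measured. That difference was −9.28 ± 44.9 points, positive in 3 of 6 clones, beside 13.3 ± 26.9 over the whole lists, positive in 4 of 6. Its value in WT clone 1 rests on 1 missing peak. A partnership of ER and OCT1 special to T-47D also stays open, since MCF-7 peaks missing with E2 overlapped the T-47D OCT1 lists by 3.25 ± 20.8 points more than the other peaks. That value ran from −14.9 in WT clone 2 to 33.2 in D538G clone 2.

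Regions rich in peaks were shared, on average over clones, by the ER and OCT1 lists of a T-47D clone. Over 147 windows of 10 Mb with at least 200 peaks each in the 6 ER E2 and the 6 OCT1 lists, the share of peaks per window, relative to the mean of the clones, correlated between the ER E2 list and the OCT1 list of the same clone at a mean of 0.468, from 0.105 in Y537S clone 1 to 0.636 in WT clone 1. The ER list of Y537S clone 1 correlated more with the OCT1 lists of D538G clone 2 (0.275) and Y537S clone 2 (0.237) than with its own, and that of D538G clone 2 as much with the OCT1 list of Y537S clone 2 (0.568) as with its own (0.570). Windows are not independent replicates, so clones were permuted: the share of 720 matchings of clones with as high a mean was 0.00139, the real one alone. This is consistent with clone-specific copy number, although shared handling of a clone's libraries is not excluded by it. Differences in list length are argued against as the whole cause, since with lists of 5769 peaks each the real matching was still the highest of the 720 (share 0.00139, the smallest possible), but the mean correlation fell to 0.278, so a part of it may follow list length. Genotype cannot be told apart from clone: the other clone of the same genotype gave 0.0387 ± 0.210 (SD, 6 pairs), below the same clone by more than the SD, but at equal length 0.118 ± 0.172, within 1 SD of it. In WT clone 1, the window on chromosome 15 at 50000001 to 60000000 held 0.34 times the mean share of ER peaks and 0.37 times that of OCT1 peaks, and the window on chromosome 12 at 90000001 to 100000000 held 1.57 and 1.85 times.

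Of the 7 OCT1 sites called in all lists but those of D538G, 5 lay on chromosome 14, from 21150812 to 102523892. They were singled out after their values were seen.

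For the site tests, 1 of 100 splits within line and genotype, the real one, gave as many sites at an unadjusted p under 0.05 for E2 against DMSO (4190, with 1137 in the highest other split). This argues against a chance split for that count, but 100 splits do not exclude it. The rank does not tell a change at single sites from longer lists. Of 100 splits that part the DMSO and E2 library of every clone, the real one alone gave as many, with a highest other of 3022, and of 1585 beside 2366 with the block on clone. Without E2, 2 of 100 splits within line gave as many as the 346 of mutants against WT. A split other than the real one gave 650, so neither a chance split nor a difference in list length can be excluded. The count was 189 without the T-47D WT clone 1 list and 194 without the MCF-7 WT clone 2 list. With E2, 25 of 100 splits gave as many as the real 117 (highest other 1157), so a chance split cannot be excluded there either. The highest other split without E2 set the long lists of T-47D Y537S and MCF-7 D538G against the rest. The highest one with E2 set the short T-47D lists of WT clone 1 and D538G clone 1, with the 2 MCF-7 WT lists, against the rest. Such splits point to a structure of the samples in list length. Longer lists alone give such counts: simulated sites with no change of their own, called at the real rates of each library, passed that level in 15.2% of cases for E2 against DMSO, beside 16.3% of the real sites, and in 4.37% for mutants without E2, beside 4.04%.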
